A study of Gallus gallus with 28 samples.

How the data were processed

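Poly(A)+ RNA from livers of lean and fat line chickens was measured on 2-colour cDNA arrays. Per the labels' protocols, total RNA of 4 chickens was pooled per sample, 500 ng of poly(A)+ RNA was reverse-transcribed with amino-allyl nucleotides and coupled to a dye, with Cy5 for the sample and Cy3 for a common reference made of all 10 pools. Since the dye orientation was the same on every array, a dye effect common to all arrays cancels in the difference between lines, while no array has the dyes swapped. Samples were grouped by line and pool from their titles.

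The deposited table holds 1 log2 ratio per spot and array, made by the authors. Scanner, background correction, spot filter, normalization and software are not given in the sources used here. The log base was inferred from the values, which reach 14.01, above the 11.1 or 4.82 that a natural log or log10 ratio of a 16-bit scanner could give. Scale and direction are not stated. The medians of the arrays lay between -0.06 and 0.07, so the arrays were taken as centred. The direction was taken as likely sample over reference from the channel order. A planned check was the correlation across clones of the mean log2 ratio with the variance between pools. It should be negative for sample over reference and positive for the reverse. It was weakly positive (Spearman rho 0.0772 over 297 clones, which are not independent replicates), so it leaned against the direction taken and did not settle it. Nor did a check added after seeing the data: the reference holds all pools, so the mean linear ratio of a clone should lie near 1, and it lay nearer 1 as deposited than with the sign turned in 112 of the 232 clones with values in all pools and in 11 of the 20 with the widest variance between pools. The 3 clones of CYP2C18, a gene picked for its small p, were nearer 1 as deposited (0.940, 1.09 and 0.818, against 1.62, 1.34 and 1.63 with the sign turned). The lowest Pearson r of any array pair was -0.271.

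The 1728 spots carry IDs of 3 numbers, read as printing block, column and row. Spots 3 rows apart held the same clone wherever an annotation was given (206 of 206 positions), so the values were averaged over 576 positions of 3 spots, called clones here. Missing values, with 36.7% of table cells filled, were left missing. Of the spots, 618 had 1 gene symbol in the platform annotation, 0 had several and 1110 had none. All 618 matched a current chicken gene entry (GRCg7b annotation, used for names only) and 0 symbols changed. Files name no genome build, so no coordinates are given. Clones of a gene were kept apart in the test of clones and averaged for gene lists. Some of them, such as those of FASN and of SCD, were the same cDNA printed at different positions. Where clones of a gene named in the text went opposite ways, the values of each or their range are given.

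Values were averaged over the 3 spots, then over the arrays of a pool. Clones with values in at least 3 pools of each line were tested: 297 clones, 152 with a name (110 genes) and 145 without. The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided moderated test, Benjamini-Hochberg) on 10 pool values, called at an adjusted p under 0.05, and differences are fat minus lean. P-values thus measure the spread between pools of 4 chickens, which includes the array error left in the pool values. Gene lists, 18 in all, were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where stated. The 10 lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01. Because of missing values this ran on the moderated statistics, and the versions with an estimated correlation and fry ran on genes with all 10 pools, 8 of 10 for the fatty acid synthesis list. No list called at the preset correlation held with an estimated one. Of the 8 other lists, 4 had 1 measured gene each: BCKDHB for amino acid metabolism (0.34, and 0.11 without pool 3), ATP5J2 for oxidative phosphorylation (-0.26, and -0.16 without pool 6), AMY1A for pancreas and intestine (-0.10, above 0 without pool 8) and CYP2C18 for cytochromes P450. The lists of erythrocyte, leukocyte, stromal and adipocyte markers had 0. ATF4 and MDH2 stood at 5 positions each.

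Named genes were, since 0 clones were called, the 5 with the smallest p in each direction (1 clone per gene, clones with a name only), 18 genes fixed by name (1 of them is not reported here) and called members of the lists. The 3 members with the smallest p of each tested list were added after the values were seen. CYP2C45 was matched to CYP2C18 by its synonym. Pools within a line were compared with a limma F test on arrays, for clones with values on at least 2 arrays of every pool. The spread between pools and list means were tested by exact permutation of the 10 pools over every split into 5 and 5, whose smallest p is 0.00794.

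Alternatives were arrays as observations (with the correlation within pools, with array number as a block, or as independent), median, quantile and scale normalization between arrays, other filters for missing values, robust variances, weights, Welch and exact tests per clone, other thresholds, medians over arrays, clones averaged by gene, single arrays per pool and leaving out each pool. Chosen after seeing the data were medians over spots, single spots, named clones only, leaving out the second array of pool 3 (which had the widest ratios, SD 1.25) or, for the pools of the lean line, the first, camera at the preset correlation on genes with all 10 pools, leaving out spots beyond 5 on the log2 scale, exact permutation of list means and the fatty acid list without FASN and SCD.

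The code was tested on simulated data with the real missing values and, for clones and lists between the lines, the real means and spreads. Each of 20 runs of 297 clones held 20 changed clones of every size together, with no correlation between clones. In these runs limma recovered 36.0% of log2 differences of 0.5, 74.0% of 1 and 95.0% of 2, and 4.87% of the calls were false. Recovery with fewer changed clones, where the adjustment is harder to pass, was not measured. With no change planted, 2 of 20 runs gave a call. With the clones of the fatty acid list shifted by 0.5 and no correlation between genes, camera called it in 100% of the runs. For the F test, values were drawn around 0 with 1 spread per pool for all clones, so clones with a wider spread were not simulated. With 1 pool shifted by 2 in 20 clones it recovered 100% in either line. Of the calls, 12.1% were false in the lean line (189 clones) and 4.53% in the fat line (202 clones). Figures were drawn with matplotlib.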

Results

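Liver gene expression was compared between a lean and a fat line of chickens (Gallus gallus) with 2-colour cDNA arrays, glass slides on which the sample competes with a reference for each printed clone. The samples were 10 RNA pools, 5 of the lean line (pools 1 to 5) and 5 of the fat line (pools 6 to 10), each made from the livers of 4 chickens. Each pool was hybridised on 3 arrays, except pools 3 and 8 with 2, giving 28 arrays. Arrays of a pool carried the same RNA and counted as 1 replicate, so n is 5 per line unless stated. Between 450 and 741 of the 1728 spots had a value on an array, with 621 ± 38.5 in the lean pools and 648 ± 49.8 in the fat pools (mean ± SD, n = 5 each, two-sided exact permutation p = 0.381). Arrays of the same pool correlated weakly over the tested clones, with a median Pearson r of 0.21 over 26 pairs, against 0.08 between pools of a line and -0.00214 between lines. The number of pools and the error between arrays both limit the precision: the median standard error of a difference between the lines was 0.20 on the log2 scale.

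The first comparison asked which genes differed between livers of the fat and lean line. The named clone with the smallest p was of CYP2C18, a cytochrome P450 whose gene entry also carries the name CYP2C45 and whose family oxidises drugs and steroids. In that clone the log2 ratio was 0.40 ± 0.35 in the lean pools and -1.10 ± 0.84 in the fat pools (SD, n = 5 each), a difference of -1.50 with a standard error of 0.37, or 2.83-fold (95% interval 1.60 to 4.98). The direction of the deposited ratio is likely sample over reference, since the liver sample sat in the first channel (Cy5) against a reference of all pools. The checks on the values did not settle this, and the planned check leaned weakly towards the reverse. If the ratio ran the other way, every direction given here would turn. The difference did not pass the limma test after Benjamini-Hochberg adjustment (adjusted p = 0.239). The second clone of the gene differed by -1.39 (standard error 0.36) and the third by -1.02 (standard error 0.37). In all 3 clones the 5 fat pools lay below the lean mean, and in the first and second no fat pool reached the lowest lean pool. FASN, the enzyme that builds palmitate, was -0.51 ± 0.41 in lean and 0.36 ± 0.39 in fat pools (SD, n = 5 each), a difference of 0.87 (standard error 0.24, limma adjusted p = 0.239). SCD, which puts the first double bond into saturated fatty acids, was -0.83 ± 0.49 in lean and 0.05 ± 0.36 in fat pools (SD, n = 5 each), a difference of 0.89 (standard error 0.25, limma adjusted p = 0.239).

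**Figure D1:**
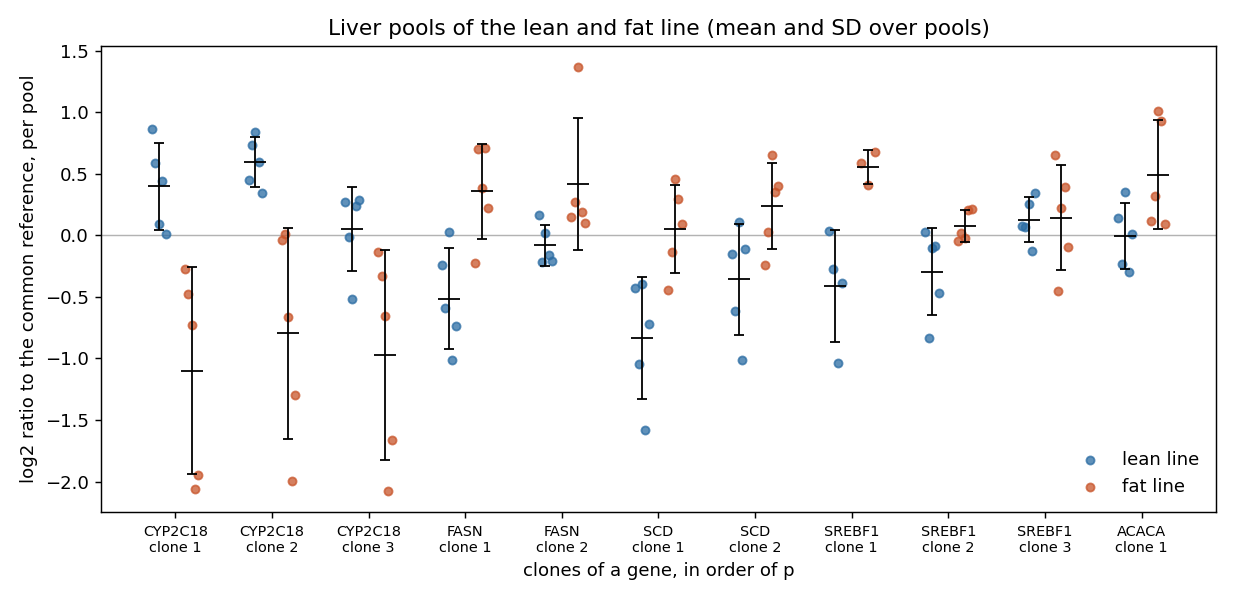
Log2 ratio to the common reference in each pool (points) for the clones of 5 genes, with the mean and SD over pools in black. All fat pools lie below the lean pools in the first and second CYP2C18 clone, while the FASN and SCD clones overlap between the lines, and the first SREBF1 clone has values in 4 lean and 3 fat pools.

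No clone passed: of 297 clones tested with limma, 0 had an adjusted p under 0.05, with 0 higher in the fat line and 0 higher in the lean line. At an unadjusted p under 0.05 there were 28, against 14.85 expected by chance, 15 higher in the fat line and 13 higher in the lean line. Without pool 8 there were 18 of 286. Exact permutation tests per clone could not bear on this, since 48 clones would have to reach their smallest p of 0.00794 for any to pass and 6 did. Fitting the arrays as observations with the correlation within pools (0.173) called 5: CYP2C18 in both clones with the larger differences, FASN, SCD and 1 clone without a gene name, which lies outside the rule for named genes and is given because it was among the 5. In that fit the first CYP2C18 clone differed by -1.55 (limma adjusted p = 0.0116, from 0.00307 to 0.484 over its alternatives). The correlation is 1 value for all clones. Both of these CYP2C18 clones may have varied between fat pools beyond array error (limma F test, unadjusted p = 0.00621 and 0.00623, adjusted p = 0.163 each). If so, the adjusted p of 0.0116 may be too small. Of the 232 clones with all 10 pools, 6 had lines that did not overlap, where chance gives 0.794%, or 1.84 clones.

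Among the other named clones with the smallest p, none of which passed, SREBF1, a transcription factor that drives lipid synthesis genes, was higher in the fat line by 0.97 (standard error 0.26, 4 lean and 3 fat pools). Its other clones, the same cDNA at other positions, gave 0.37 (0.24 without pool 2) and 0.02. The last changed sign without pool 4, 6, 8 or 9 (-0.11 without pool 6). ACACA, which makes malonyl-CoA for fatty acid synthesis, differed by 0.50 (standard error 0.22). MDH2, the mitochondrial malate dehydrogenase, differed by 0.37 in its clone with the smallest p, and its 5 clones ran from -0.37 (-0.21 without pool 3) to 0.52. In the other direction, RPS4Y1 and RPS25, proteins of the small ribosomal subunit, differed by -1.36 (standard error 0.48) and -0.41 (standard error 0.16). PM5 differed by -1.30 (standard error 0.51, 4 lean and 3 fat pools), and by -0.82 without pool 7. PNPLA3, an acylhydrolase of lipid droplets, differed by -0.48 (standard error 0.20). Their limma adjusted p-values lay between 0.239 (SREBF1) and 0.524 (ACACA).

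**Figure D2:**
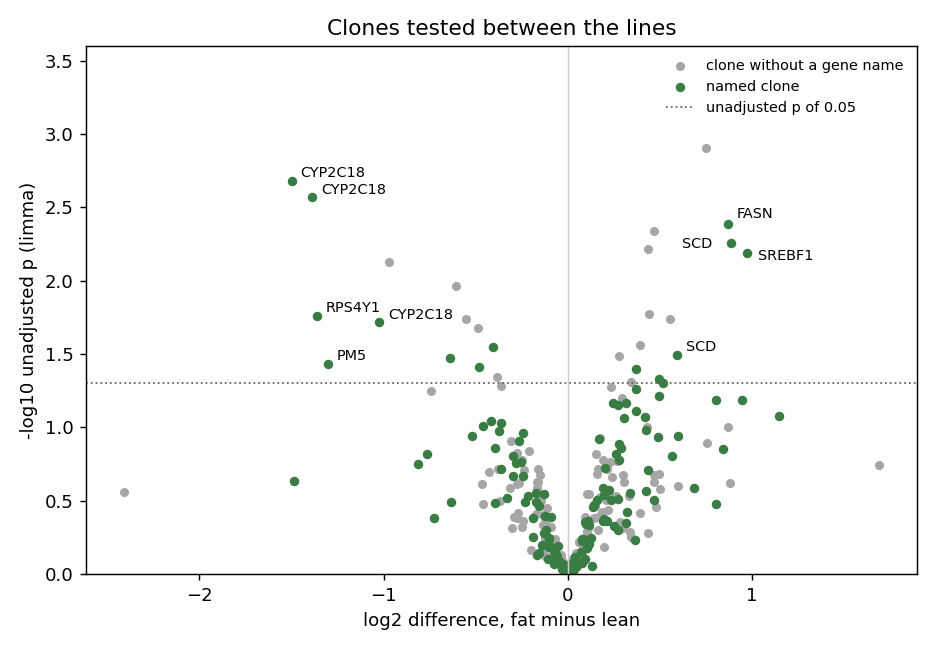
Difference in log2 ratio (fat minus lean) against the unadjusted limma p on a -log10 scale for the 297 clones tested, with clones that have a gene name in green. The 28 clones above the dotted line have an unadjusted p under 0.05, and 0 pass after adjustment.

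The second comparison asked whether groups of functionally related genes differed. Fatty acid synthesis and its regulators was the only list of 10 tested that passed: 8 of its 10 measured genes were higher in the fat line, with a mean difference of 0.30 and a median of 0.33 (limma camera with a preset correlation, adjusted p = 0.00819). The correlation estimated between the members with values in all pools was 0.443, far above the preset 0.01, so this adjusted p may be too small. The call was lost with the correlation estimated from the data (limma camera adjusted p = 0.273 with an estimated correlation) and with fry (limma adjusted p = 0.160). Both ran on the 8 members with values in all pools, whose mean was 0.40 and which passed at the preset correlation (limma camera adjusted p = 6.01e-04). In an exact permutation of the pools, 11 of all splits into 5 and 5 gave a list mean as large (two-sided exact p = 0.0873, or 0.291 after adjustment over the lists, where 1 list alone could not go below 0.0794). The averages over the members were -0.15 ± 0.27 in the lean pools and 0.16 ± 0.16 in the fat pools (SD, n = 5 each). Averaged over clones, SCD differed by 0.74, FASN by 0.68, ACACA by 0.50 and SREBF1 by 0.35, and these 4 had an unadjusted limma p under 0.05. Of the 10 members, 0 passed over all genes and 0 passed when adjusted over the list alone (smallest limma adjusted p = 0.0566), where 2 passed without pool 3 or pool 6. FADS2, a desaturase of polyunsaturated fatty acids, differed by 0.43 (0.24 without pool 8) and ELOVL6, which elongates palmitate, by 0.30 (0.18 without pool 9). THRSP (0.09), NR1H3 (0.10), TALDO1 (-0.01) and PGD (-0.15) lay closer to 0, and each turned with 1 pool left out: THRSP without pool 4, NR1H3 without pool 5 or 7, TALDO1 without pool 5, 8 or 9 and PGD without pool 1 or 10. The number of members higher in the fat line was thus 7 to 9 of 10 with each pool left out. Without pool 2, 4 or 8 the list no longer passed (limma adjusted p = 0.0737, 0.0737 and 0.0750), with means of 0.26, 0.20 and 0.23. It did not pass either without FASN and SCD (mean 0.20 over 8 genes, limma adjusted p = 0.176), a setting chosen after seeing the data. Markers of blood, immune, stromal and fat cells among the fixed lists had 0 named clones on the array, so the cell makeup of the livers was not analysed here.

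**Figure D3:**
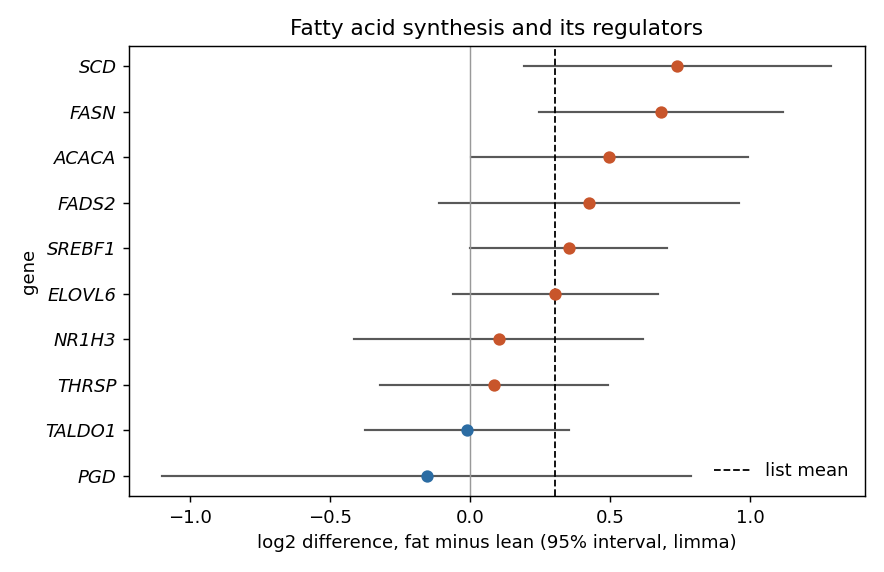
Difference in log2 ratio (fat minus lean) of the 10 measured genes of the fatty acid synthesis list, averaged over the clones of a gene, with 95% intervals from limma and the list mean of 0.30 dashed. SCD (0.74) and FASN (0.68) lie highest and PGD (-0.15) lowest.

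The ribosomal proteins and translation factors had a mean of -0.45 over 4 genes, 3 of them lower in the fat line, and did not pass (limma camera adjusted p = 0.134, exact permutation p = 0.0238 before and 0.238 after adjustment over the 10 lists). RPS25 (-0.52) and RPS4Y1 (-1.36) were the lowest. With the first array of each pool only, RPS4Y1 was at -0.38 and the RPS25 clone with the smallest p at -0.14 (-0.41 with all arrays), and with the second only at -1.29 and -0.78. Near 0, EIF4EBP1, an inhibitor of translation initiation, was at 0.11 (clones at 0.32 and -0.10) and EEF1B2 at -0.03 (clones at -0.09 and 0.04). With single pools left out EIF4EBP1 ran from 0.02 (pool 8) to 0.23 (pool 7), and EEF1B2 turned without pool 1, 7 or 8. When adjusted over the list alone 2 of the 4 passed in limma (RPS25, adjusted p = 0.0273, and RPS4Y1, adjusted p = 0.0352), against 0 over all 110 genes. Without pool 1, 2 or 9 only 1 of them passed over the list alone, and without pool 8 or 10 there were 0. For the fatty acid oxidation list the mean was 0.31 over 5 genes, 3 of them higher in the fat line, with CPT2 of the mitochondrial carnitine shuttle at 0.95 and the nuclear receptor PPARA at 0.69 (limma camera adjusted p = 0.849). ACAT1 was at -0.14, from -0.28 (without pool 3) to -0.05 (without pool 1). Without pool 3 the mean of this list was 0.17, with CPT2 at 0.59 and PPARA at 0.38. CPT2 was also lower without pool 10 (0.62), and PPARA was at 1.13 without pool 2. Genes of glycerolipid synthesis and lipid droplets had a mean of -0.10 over 5 genes, with PNPLA3 at -0.48, the liver fatty acid binding protein FABP1 at -0.25 and LBFABP at 0.27 (limma camera adjusted p = 0.567). The mean was -0.18 without pool 4, -0.04 without pool 5 and -0.05 without pool 9. LBFABP had values in 3 fat pools and no settled direction: it turned to -0.07 without pool 8 and was at 0.67 without pool 9, 0.42 without pool 1 and 0.09 without pool 4. The cholesterol synthesis list had a mean of 0.07 over 4 genes, with HMGCS1 at 0.29, STARD4 at 0.22 and SREBF2 at -0.19 (limma camera adjusted p = 0.851). The mean fell to 0.02 without pool 9, 0.03 without pool 8 and 0.04 without pool 4, and was 0.13 without pool 7. HMGCS1 was at 0.18 without pool 3 and 0.19 without pool 9, STARD4 at 0.15 without pool 8 and 0.36 without pool 7, and SREBF2 at -0.32 without pool 1, -0.08 without pool 3, -0.09 without pool 5 and -0.12 without pool 10.

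For lipoprotein components the mean was 0.13 over 4 genes, with APOA1, the main protein of high-density lipoprotein, at 0.43, LCAT at 0.09 and LRP1 at -0.03 (limma camera adjusted p = 0.849). Without pool 7 the mean was 0.07 and APOA1 at 0.14, and without pool 8 the mean was 0.20 and APOA1 at 0.72. LCAT was at 0.06 without pool 1, 4 or 8, and LRP1 turned without pool 8. Glycolysis, gluconeogenesis and glycogen had a mean of 0.07 and a median of -0.02 over 15 genes, with 7 higher and 8 lower in the fat line (limma camera adjusted p = 0.851). GAPDH (0.80) and PDHA2 (0.37) had the smallest p among them, with FBP1, an enzyme of gluconeogenesis, at 0.42. The mean was 0.02 without pool 2 and 0.13 without pool 3, where 10 of the 15 were higher. GAPDH was at 0.49 without pool 6, PDHA2 at 0.22 without pool 2 and FBP1 at 0.27 without pool 9. The plasma protein list had a mean of 0.05 over 5 genes, with CFI at 0.17, AHSG at -0.30 and GC at 0.12, whose clones went opposite ways at 0.49 and -0.26 (limma camera adjusted p = 0.851). Its mean had no settled sign, at -0.03 without pool 1, -0.01 without pool 6 and up to 0.11 without pool 5. AHSG was at -0.15 without pool 5 and -0.20 without pool 8. GC ran from 0.02 (without pool 6) to 0.20 (without pool 7), with its clones at 0.29 without pool 6 and -0.16 without pool 3. Stress proteins averaged -0.07 over 3 genes, with HSP90AA1 at -0.24, CAT at 0.16 and ATF4 at -0.11 over 5 clones between -0.36 and 0.04 (limma camera adjusted p = 0.849). The mean was -0.04 without pool 6 and -0.10 without pool 9, HSP90AA1 was at -0.13 without pool 10, and ATF4 was at -0.03 without pool 6 and -0.21 without pool 10. The growth factor and hormone list had a mean of -0.10, a median of 0.12 and an upward test direction over 6 genes (limma camera adjusted p = 0.913). IGF2 was at 1.15 (0.41 without pool 5) and IGF1 at -0.81 (-0.21 without pool 3, -1.23 without pool 2), each in 3 lean and 4 fat pools. The direction of IGF1 was not settled, since it turned to 0.62 without the second array of pool 3 or without spots beyond 5 on the log2 scale. THRA was at -1.48, with a lean SD of 2.98 because pool 3 stood at 6.765. Without that array of pool 3, or without spots beyond 5, THRA was at -0.04. Without pool 3 THRA was at -0.17 and the list mean was 0.27, while with any other pool left out the mean lay between -0.25 (pool 2) and -0.05 (pool 10). Apart from the ribosomal list, 0 members of the lists tested passed when adjusted over the list alone with all pools, and without pool 10 there was 1 in the glycerolipid list.

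Of the remaining genes fixed for reporting, THRSP, a lipogenic protein induced by thyroid hormone, gave 0.23 and -0.06 in its clones, the first at 0.14 without pool 8, 0.15 without pool 4 and 0.41 without pool 6, and the second turning without pool 3 (0.11) or pool 6. APOB, the structural protein of very low density lipoprotein, differed by 0.03 (standard error 0.13, 95% interval -0.26 to 0.33), and turned without pool 4, 9 or 10. FABP1 had 5 clones between -0.46 and -0.03, of which the last had no settled sign (0.22 without pool 3, -0.27 without pool 2). GAPDH was 0.06 ± 0.45 in lean (SD, n = 5) and 0.87 ± 0.83 in fat pools (SD, n = 4), a difference of 0.80 with a standard error of 0.39 (limma adjusted p = 0.530), and 0.49 without pool 6. The 1 ALB clone had no value on any array. ACLY, ME1, MLXIPL, CPT1A and CYP7A1 were not among the named clones.

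Other settings also moved named clones by over 1.5 times. With the first array of each pool only, SCD differed by 0.58 (0.89 with all arrays), PNPLA3 by -0.10 (-0.48), FABP1 by -0.67 (-0.36), EIF4EBP1 by 0.49 (0.32), CAT by 0.39 (0.20), LCAT by 0.26 (0.09), APOB by 0.18 (0.03), THRSP by 0.10 (0.23) and ACAT1 by -0.02 (-0.17), while STARD4 (0.22), LRP1 (-0.05) and the ATF4 clone with the smallest p (-0.36) changed sign. With the second array only, THRA differed by -3.91, ATF4 by -0.85, GC by 0.85 (0.49), THRSP by 0.58, CPT2 by 0.38 (0.95), LRP1 by -0.30, ACAT1 by -0.29, PDHA2 by 0.21 (0.37), APOB by 0.08 and HSP90AA1 by -0.02 (-0.24), while LCAT changed sign. Without the second array of pool 3 SREBF2 was at -0.01 (-0.19), ATF4 at -0.22 and LCAT at 0.25, and LRP1 changed sign. With quantile normalization APOA1 was at 0.82 (0.43), THRA at -0.83, IGF1 at -0.29 and THRSP at 0.12. With the array number as a replicate block SREBF1 was at 0.45 (0.97), APOA1 at 0.15, AHSG at -0.53 (-0.30), THRA at -2.38 and LBFABP near 0 (0.00124). With arrays as independent observations GAPDH was at 0.51 (0.80), CPT2 at 0.61, APOA1 at 0.26, SREBF2 at -0.12 and IGF1 at -1.23. Medians over arrays gave 0.02 for THRSP, -0.22 for ATF4 and -0.12 for LRP1, medians over spots 0.11 for CFI (0.17), and weights per pool -0.68 for THRA, -0.50 for IGF1 and -0.11 for SREBF2.

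The third comparison asked how far pools of one line, made from different chickens, differed beyond the error between arrays. In the lean line GYS2, the liver glycogen synthase, was the 1 clone of 189 that passed (limma F test, adjusted p = 0.00255): pool 3 stood at 1.98 and the other pools between -0.23 and 0.08. At an unadjusted p under 0.05 there were 30 clones, against 9.45 expected. In the fat line 0 of 202 clones passed in limma (smallest adjusted p = 0.0536) and 46 had an unadjusted p under 0.05, against 10.1 expected. CYP2C18 was among these: its first clone stood at -2.06 in pool 9 and -1.95 in pool 10, against -0.28, -0.48 and -0.73 in pools 6, 7 and 8 (limma F test, adjusted p = 0.163). These tests cover array error only. Pool 3 rested on 2 arrays that did not correlate (r = -0.07), and without it 0 lean clones passed. GYS2 stood at 1.83 on the first and 2.12 on the second of them. Fits with either left out were chosen after seeing the data. They left pool 3 with 1 array, so its own array error was not covered and their calls do not bear on GYS2. Of the other clones called there, ITIH3 stood at 0.37 and 0.34 on the first and second array and IDH2 at -0.46 and -1.53. ENO1 stood at -0.90 and 2.61, SEC61A1 at 1.69 and 0.12, and unnamed clones at 1.68 and -7.06 and at 1.56 and -0.04.

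The spread between pools was also compared. Lean pools deviated from their line mean by a root mean square of 0.477 ± 0.152 and fat pools by 0.383 ± 0.0300 (SD, n = 5 each), a difference of -0.0935 that an exact permutation test did not separate from chance (two-sided exact p = 0.611). Pool 3 had 0.742, and without it the difference was 0.0288 (two-sided exact p = 0.325).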

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

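All tests of this part were chosen after the result was seen, except the count of lists over other splits and the comparisons with other clones of the same printing blocks. In 91 groups of 4 or 5 pools of a line, 6 had a pool far from the others, where chance gives 4.55. Lean pool 3 was the one in 3 of these: THRA at 6.765 against -0.21 to 0.84 in the other lean pools, 1 of the 5 ATF4 clones at -0.40 against 0.34 to 0.63 and the root mean square deviation from the line mean at 0.742 against 0.373 to 0.465. The other 4 ATF4 clones stood between -0.10 and 0.83 in pool 3, and the mean of the 5 was 0.16 there, against 0.19 ± 0.11 over the lean pools (SD, n = 5). In the fat line, ELOVL6 stood at 0.60 in pool 9 against -0.11 to 0.03, CPT2 at 1.77 in pool 10 against -0.12 to 0.395, and HSP90AA1 at -0.71 in pool 10 against -0.25 to -0.09.

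The higher values of the fatty acid synthesis list in the fat line (mean 0.30) were weighed first. In the deposited values the printing blocks that hold the members did not carry the difference: 132 other clones of these blocks gave -0.0478 (standard error 0.0409, over clones). This does not decide on a block shift, since centring by block before deposit may have brought the value near 0. An array-wide shift was not tested by the pool medians (fat minus lean 0.0268), since the deposited arrays were centred and this value was bound to lie near 0. Chance stays open, since 13 of 100 splits of the pools called at least 1 list (real value 1, highest of the others 1). A difference in lipid synthesis between the lines also stays open and may be small next to the spread between pools.

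The lower values of CYP2C18 in the fat line had a mean of -1.30 over 3 clones. The gene was picked for its small p, which a difference from 1 pool would hardly give. Leaving out single pools was thus a weak test of a single pool as the cause. Without pool 9, which weakened the difference most, it was -1.03 (standard error 0.34), above 0.5 times its size. In the deposited values the printing blocks did not carry it, since 43 other clones of the same blocks gave 0.10 (standard error 0.03, over clones). Centring by block before deposit may likewise have brought this value near 0. The fat pools differed by 1.89 from lowest to highest and the lean pools by 0.39. This does not decide on a sequence variant of the fat line. Pools hold different birds, which may vary beyond array error with or without one. Such a variant, hybridisation of related P450 transcripts and a difference in expression between the lines or among fat birds stay open, as untested.

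The 28 clones at an unadjusted p under 0.05 exceeded the count in most of 100 drawn splits of the pools. Of these splits, 2 gave as many, the real one included, and the highest of the others also gave 28. Clones were filtered by the real lines, and those with too few values in a group were left out of another split. Other splits could thus test fewer clones. Without pool 8 the count was 18. That other split set pools 1, 7, 8, 9 and 10 against the rest, so it differed from the real one only by exchanging pools 1 and 6. Splits say nothing about the 0 clones called after adjustment, or the 0 higher in the fat line, since a count of 0 is reached by each of the 100 splits (highest of the others 0).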

How the results depend on the processing

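The settings with single spots, without FASN and SCD, with exact permutation of list means, with camera at the preset correlation on genes with all pools and without an array of pool 3 or spots beyond 5 were chosen after seeing the data. No normalization, filter, variance model or Welch test on pool values called a clone between the lines, nor did leaving out the second array of pool 3 or testing single spots, and leaving out each pool gave 0 to 0 clones, with 0 to 0 higher in the fat line. An exact test per clone could not pass here, since 48 clones would have to reach its smallest p of 0.00794 and 6 did. Arrays as observations with the correlation within pools gave 5 clones (3 higher in the fat line) and arrays taken as independent 8 (5 higher), as more observations enter than pools. With a replicate block for the array number there were 6 (3 higher), and 2 clones differed between pools of the fat line. The array number was not taken to pair the samples in the main test. Deviations of same-numbered arrays correlated at a mean of 0.03, against -0.01 for others, with a lowest value of -0.27. A lowest value among many pairs does not decide on pairing. As a hint towards pairing, 16 of 28 arrays lay closest to their own number, against 9.23 on average with numbers permuted within pools (permutation p = 0.055). At an unadjusted p under 0.05 there were 28 clones (15 higher) and 2 lists.

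The fatty acid synthesis list kept its direction in all 39 settings (0.20 to 0.40) and its call in 32, all with the preset correlation of 0.01. The adjusted p ran from 5.91e-04 to 0.291 over the limma and permutation tests, with 0.273 for camera with an estimated correlation. Leaving out each pool gave 0 to 1 called lists and means of 0.20 to 0.37. No list passed with an estimated correlation (0 lists, mean 0.40 over 8 genes) or fry (0, 0.40 over 8), while the preset correlation on these 8 genes kept the call, so the genes left out did not end it. None passed without FASN and SCD, its largest members (0, 0.20 over 8 genes), or with exact permutation of the pools (0, 0.30), where 2 lists would have to reach the smallest p for any to pass. Single spots called 2 lists. Other causes were not tested.

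Clones that differed between pools of the lean line numbered 0 with a value on every array (fewer clones tested) and 0 to 3 with each pool left out. Leaving out the first or the second array of pool 3 left that pool with 1 array, so a count from such fits does not cover its array error. In the fat line there was 1 with array medians set to 0, 2 with a value on every array and 0 to 2 with each pool left out. The cause was not tested. The spread between pools, fat minus lean, turned to 0.0152 with a value on every array and ran from -0.121 to 0.0288 with each pool left out, turning without pool 3. The correlation behind the direction check ran from 0.0111 to 0.130 with each pool left out, so it stayed on the side of the reverse direction.

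Of 1093 values of 36 named genes under other settings, 1063 kept direction and side of the threshold, 19 passed a threshold and 11 turned, all in 6 genes that did not pass. Other thresholds, robust variances and Welch or exact tests leave the difference itself unchanged, so these settings could not turn a direction. The 19 hold only values at the unadjusted p under 0.05 and calls with arrays as observations. APOB turned with medians over arrays (-0.00133) and without pool 4, 9 or 10 (range with each pool left out -0.0356 to 0.0925), LRP1 with first arrays only (0.0297) and without the second array of pool 3 (0.0414), STARD4 (-0.00792) and ATF4 (0.12) with first arrays only, LCAT with second arrays only (-0.15), and IGF1 without the second array of pool 3 (0.62) and without spots beyond 5 (0.62). LBFABP also turned without pool 8 (-0.07), where only 2 fat pools were left and no test was run. The cause was not tested. Signal over background was not analysed here.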

Other observations

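The tests of this part were chosen after the values were seen. SLC27A2, a fatty acid transport protein and very long chain acyl-CoA synthetase outside the fixed lists, was higher in the fat line at each of its 4 tested positions (0.84, 0.27, 0.26 and 0.08), none of which passed the limma test. Each rested in part on single pools: the first was 0.36 without pool 3, the second 0.03 without pool 2, the third 0.13 without pool 3 and the fourth 0.03 without pool 2 or 7. The beta-defensin AvBD8 gave 0.28 and -0.13 (-0.06 without pool 2) at its positions. AvBD9, another antimicrobial peptide of this family, had values in 4 lean and 0 fat pools at both of its positions. These came from 5 and 6 arrays in all, so most lean arrays had no value either. In all, 4 clones had values in 4 or 5 pools of one line and none of the other, and 5 of all splits of the pools into 5 and 5 gave as many.

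The same cDNA printed at different positions gave a measure of agreement. For 21 cDNAs at 2 or more tested positions, the differences between the lines correlated across cDNAs, taking 1 pair of positions each (Pearson r = 0.868, Spearman rho = 0.719, permutation p = 7e-04 for rho). Such positions share the same arrays, so this is across genes, which are not independent replicates. Over all 29 pairs, 21 had the same sign and the median disagreement was 0.188 on the log2 scale. SREBF1 had the widest disagreement, with 0.97 at one position and 0.02 at another.

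Of the 1728 spots, 598 had no value on any array. The 1 ALB position had none, and 8 of 9 APOA1 positions had values on 3 or fewer arrays.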
